A study of Mus musculus with 4 samples.

How the data were processed

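Chromatin immunoprecipitation followed by sequencing (ChIP-seq) maps where a DNA-bound protein sits on the genome. Here it was applied to cells dissociated from the trunks of wild-type C57BL/6 mouse embryos at embryonic day 11.5. The series used here holds 4 libraries: 1 with antibodies against Meis1/2, 1 with an antibody against Prep1/2, and 1 input library without antibody for each. Each of these groups has 1 library, so nothing measures the spread between embryos or between repeat experiments. A peak list was used for each of the 2 antibody libraries; the input libraries and any further protein of the series were not analysed here.

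Reads were aligned with BWA to the mm9 build, per the submitters' processing notes. Peaks were called once per antibody library, and the peak names carry the tag "pics", per the file headers and columns. The version of the aligner, the caller's settings, the use of the input in the calling and any later filter are not given in the sources used here. The deposited value of each peak is a score, which is the authors' own value from their peak caller. It has no stated scale and is not a count. Scores were compared within a list; between the lists they were set side by side only after each was divided by its own step, the interval between its most frequent scores, which was chosen after the data were examined. In both lists the order of the scores followed the number in the peak names without exception. The numbers run to 5692 in the Meis list and to 3338 in the Prep list, and 6 and 7 of them have no peak in the lists used here. Read totals are unknown, so no depth could be set beside a peak. The counting intervals given below cover the number of peaks only.

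Peak starts were raised by 1 so that positions count from 1, on the assumption that the lists follow the BED convention, which their headers do not state. All positions are mm9. The gene table at hand belongs to another build (GRCm38.p6), and no mm9 sequence or annotation was used here. Peaks were therefore named by position and assigned to no gene, exon or promoter. The comparisons of promoter shares, of 16 fixed sequence motifs and of 25 fixed gene lists were planned before the data were examined and were not run for this reason. A random placement that keeps the distance to genes was not run either.

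Peaks of the lists were called shared when they overlapped by at least 1 bp, and otherwise Meis-only or Prep-only. The number shared was compared with 1000 random placements of the Prep peaks. Each peak kept its width and its chromosome and was placed between the first and the last peak of both lists on it (one-sided permutation test; the smallest p this allows is 0.001). Scores and widths of shared and exclusive peaks were compared within a list by the difference of medians. A two-sided permutation test with 100000 resamples was used (smallest p 1e-05), with Benjamini-Hochberg adjustment over the 4 tests and 95% bootstrap intervals from 2000 samples. The place of a peak is its position in its list in order of score, 1 being the highest. Shares of peaks carry 95% Wilson intervals. Dense groups of peaks, called runs, were stretches of at least 4 peaks of one list with gaps of up to 10 kb, and their number was compared with 1000 random placements. The chromosomes of the lists were compared by a chi-square statistic with permuted list labels, and chromosome by chromosome with Fisher's exact test, adjusted over 21 chromosomes. The comparison of chromosomes, of distances to the nearest peak, of 10% slices of the lists and of the shared part of the runs was added after the data were examined. Peaks are not replicates, so every p-value compares these 2 lists and not Meis with Prep binding in general.

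The peaks named in the text were fixed by rule before the data were examined. They are the 3 highest-scoring peaks each of the Meis-only and Prep-only classes, the 3 shared pairs whose weaker place is best, and the 5 runs with most peaks in each list, ties going to the higher top score. Any other named peak was chosen after its values were seen, and the text says so. The alternatives were a stricter list (the highest-scoring 50%), equal list lengths, other overlap rules, a fixed peak width of 200 bp, autosomes only and wider gaps. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The procedures were tested on simulated lists with the real numbers of peaks, widths and chromosomes. With 300 overlapping Prep peaks planted among 3331, 305 were found, against 5 with none planted. With 10 runs planted in the Meis list, 10 were found, against 0 with none planted.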

Results

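Meis and Prep are homeodomain transcription factors of the TALE class, and both act as partners of Pbx proteins. Their binding was profiled in the trunk of the mouse embryo at embryonic day 11.5, 1 library per antibody. The Meis list held 5686 peaks on 20 chromosomes and the Prep list 3331 peaks on 21. Peaks were narrow in both lists. The median width was 209 bp for Meis (quartiles 187 and 232 bp) and 244 bp for Prep (quartiles 189 and 286 bp). In all, 1202 kb were called for Meis and 821 kb for Prep, summed over peaks. Scores of Meis peaks ran from 8.51 to 75.1, with a median of 10.7. Those of Prep peaks ran from 5.03 to 353, with a median of 10.5 and an upper quartile of 43.3. The scores are the authors' values on a scale that was not stated, and peaks were set against each other by score within a list. Scores were compared between the lists only in the places that say so, after scaling each list to its own score step.

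The first comparison asked how far the Meis and Prep peaks coincide in the same tissue. Most peaks were found in one list alone. Of the Meis peaks, 407 overlapped a Prep peak, which is 7.16% (95% Wilson interval 6.52 to 7.86%), and 5279 did not. Of the Prep peaks, 408 overlapped a Meis peak, which is 12.2% (11.2 to 13.4%), and 2923 did not. Signal below the lowest listed score, 8.51 for Meis and 5.03 for Prep, does not appear in the lists. A peak found in one list alone may thus have weaker signal of the other protein. Random placement of the Prep peaks on the same chromosomes gave 3.58 overlapping Prep peaks on average and 10 at most, so the observed number was 114 times the average (one-sided permutation p = 0.001 over 1000 placements, the smallest they can give). When Prep peaks were instead moved by only 10 to 100 kb from their own position, 5.49 overlapped on average and 17 at most.

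The overlapping peaks lay almost on top of each other. They formed 409 pairs, and the centres of a pair were a median of 28.5 bp apart (quartiles 13 and 53 bp), with 299 pairs (73.1%) within 50 bp. In 351 pairs the Prep peak was the wider one. The pair with the best places in both lists lay on chromosome 9, where the Meis peak at 61218275 to 61218434 was 5th in its list with a score of 65.8. The Prep peak at 61218292 to 61218452 was 190th with a score of 148, and the centres were 17.5 bp apart. The next pair lay on chromosome 19, with the Meis peak at 5688928 to 5689093 (place 347, score 20.8) and the Prep peak at 5688841 to 5689003 (place 354, score 111). The following one lay on chromosome 10, with the Meis peak at 81033733 to 81033889 (place 323, score 21.3) and the Prep peak at 81033727 to 81033885 (place 531, score 81.4).

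Shared sites ranked differently in the lists. Shared Meis peaks were among the stronger Meis peaks, with a median score of 14.3 against 10.7 for Meis-only peaks, a difference of 3.58 (95% interval 2.93 to 4.32; adjusted permutation p = 1.33e-05). Shared Prep peaks were among the weaker Prep peaks, with a median score of 7.88 against 11.8 for Prep-only peaks, a difference of -3.94 (-5.25 to -2.63; adjusted permutation p = 0.00019). The median place of a shared peak was 1237 of 5686 in the Meis list and 2096.5 of 3331 in the Prep list. Within the part of the Prep list whose scores match or exceed the lowest Meis peak after scaling each list to its own score step, 92 of 1335 peaks were shared and the difference of -10.5 did not pass the test (permutation p = 0.185, -23 to 3.94); the Meis difference was then 1.23 (0.115 to 2.81).

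**Figure D1:**
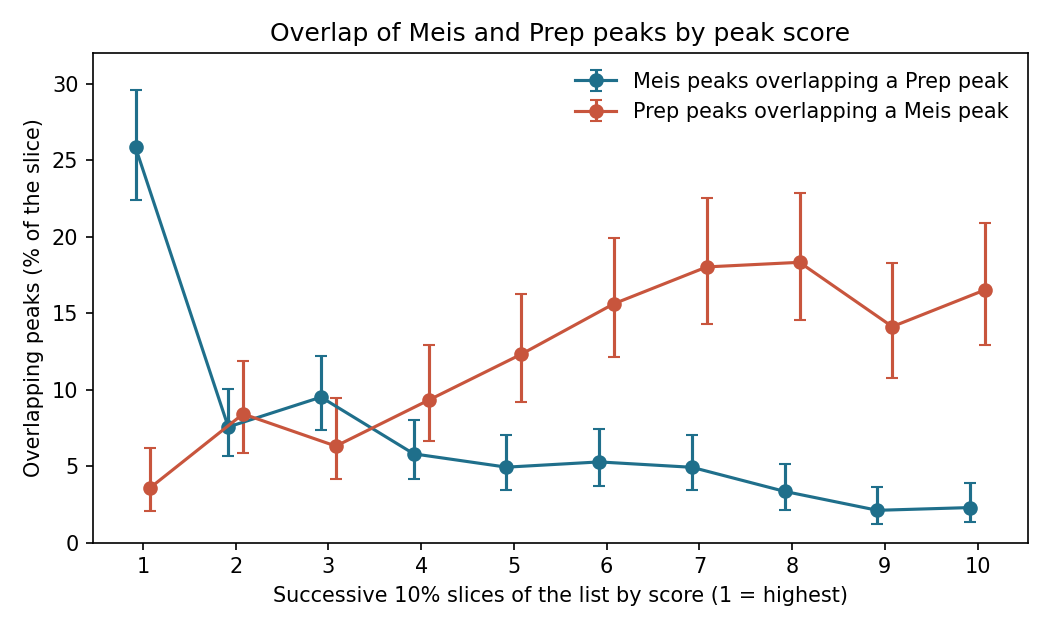
Share of peaks that overlap a peak of the other list (y axis, percent) in successive 10% slices of the Meis list and of the Prep list by score (x axis, 1 is the highest-scoring slice); points are shares and bars 95% Wilson intervals, which cover the number of peaks only. The Meis share is 25.8% in the highest-scoring slice and 2.29% in the lowest, while the Prep share is 3.59% in the highest and 16.5% in the lowest.

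Ordered by score, the share of Meis peaks with an overlapping Prep peak was 25.8% (22.4 to 29.6%) in the highest-scoring 10% of the list (569 peaks) and 2.29% (1.34 to 3.88%) in the lowest (Fisher's exact test, two-sided, adjusted p = 2.1e-33). For Prep it was 3.59% (2.07 to 6.17%) in the highest-scoring 10% (334 peaks) and 16.5% (12.9 to 20.9%) in the lowest (Fisher's exact test, adjusted p = 1.26e-08). Among the 100 highest peaks of each list, 53 Meis peaks and 4 Prep peaks were shared (Fisher's exact test, adjusted p = 2.04e-15). Of the 10 highest Meis peaks 8 were shared, and of the 10 highest Prep peaks 1 was. Some of these were chosen after their values were seen. The 2nd Meis peak, on chromosome 4 at 150132706 to 150132887 with a score of 71.3, met a Prep peak with a score of 7.88 at place 2144. The 3rd Meis peak, on chromosome 15 at 103135727 to 103135883 with a score of 70.9, met a Prep peak with a score of 56.5 at place 703. The shared Prep peak among the 10 highest, on chromosome 19 at 12040010 to 12040204, had a score of 301, and its Meis partner had a score of 9.05 at place 4635.

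Across the 409 pairs, the scores of the partners did not rise together. Spearman's rho was -0.08 (95% bootstrap interval -0.17 to 0.02; permutation p = 0.122, the same after adjustment) and Pearson's r of the log2 scores was -0.15 (permutation p = 0.00308, adjusted 0.00616). Without the 2 pairs farthest from the median Meis score, r was -0.16. These coefficients are across peaks, which are not independent replicates.

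The strongest Meis-only peak was also the strongest Meis peak of all. It lay on chromosome 11 at 18774599 to 18774780 with a score of 75.1. It was followed by a peak on chromosome 8 at 27881020 to 27881202 (score 58.7, place 8) and one on chromosome 14 at 22723635 to 22723847 (score 46.8, place 17). The 3 strongest Prep-only peaks held the first places of the Prep list. They lay on chromosome 3 at 89215800 to 89215949 (score 353), on chromosome 7 at 52241861 to 52242053 (score 349) and on chromosome 17 at 85356898 to 85357087 (score 332).

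Shared and exclusive peaks also differed in width, in opposite directions. Shared Meis peaks were narrower than Meis-only peaks, with medians of 197 and 210 bp, a difference of -13 bp (-16 to -9). Shared Prep peaks were wider than Prep-only peaks, with medians of 268 and 239 bp, a difference of 29 bp (19 to 35). Both differences had an adjusted permutation p of 1.33e-05. The Spearman coefficient of width with score across peaks was -0.87 (-0.88 to -0.86) in the Prep list and -0.13 (-0.15 to -0.10) in the Meis list. The lists spread differently over the range of scores, so the coefficients cannot be set against each other. The median Prep peak was 165 bp wide in the highest-scoring 10% and 301 bp in the lowest, and the corresponding Meis widths were 196 and 216 bp. Where the lists cover the same range after scaling to their score steps, widths were compared in separate ranges of steps. Within these ranges the median widths differed by at most 15 bp. Prep minus Meis was 1 bp (-2 to 4.01) from 24.7 to 50 steps and -11 bp (-15 to -8.5) from 50 to 100. From 100 to 218 steps it was -15 bp (-26 to -11).

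Prep-only peaks were nearer to Meis peaks than random placement gave. Of the 2923 Prep-only peaks, 51 had a Meis peak centre within 1 kb against 13.5 expected, 184 within 10 kb against 125 expected, and 1130 (38.7%) within 100 kb against 892 expected. Each of these counts exceeded all 1000 placements (one-sided permutation p = 0.001, adjusted over 9 tests 0.00112). The ratio of observed to expected thus went from 3.79 at 1 kb to 1.47 at 10 kb and 1.27 at 100 kb. For the Prep-only peaks of the higher-scoring 50% of the list, the ratios at these distances were 4.13, 1.36 and 1.26, and for those of the lower-scoring 50% they were 3.38, 1.57 and 1.28; the differences between them were not tested. The higher-scoring peaks within 10 kb numbered 90, below the highest placement of 96 (one-sided permutation p = 0.003). These placements spread peaks evenly over the span of a chromosome, and moving Prep peaks by 10 to 100 kb was not tried here. The counts thus do not tell nearness to Meis peaks from peaks of both lists lying in the same parts of a chromosome.

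Peaks of both lists gathered in dense runs. The Meis list held 13 runs of at least 4 peaks with gaps of up to 10 kb, which took in 78 peaks, against 0.089 runs expected and 1 at most under random placement (one-sided permutation p = 0.001). These placements spread peaks evenly over the span of a chromosome. They do not allow for parts of it that are richer in peaks, and moving peaks by 10 to 100 kb was not tried for runs. The 5 runs with most peaks were 2 stretches of chromosome 6 and 1 each of chromosomes 11, 18 and 2. The first held 11 Meis peaks over 20.3 kb, at 52108281 to 52128618 on chromosome 6. A second run of 9 peaks over 35.7 kb followed on the same chromosome at 52140862 to 52176538. The run on chromosome 11 at 96180588 to 96213320 held 10 peaks. The run on chromosome 18 at 84236664 to 84256016 held 9 peaks, with the 13th Meis peak of the list among them. The run on chromosome 2 at 74572564 to 74591402 held 6.

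**Figure D2:**
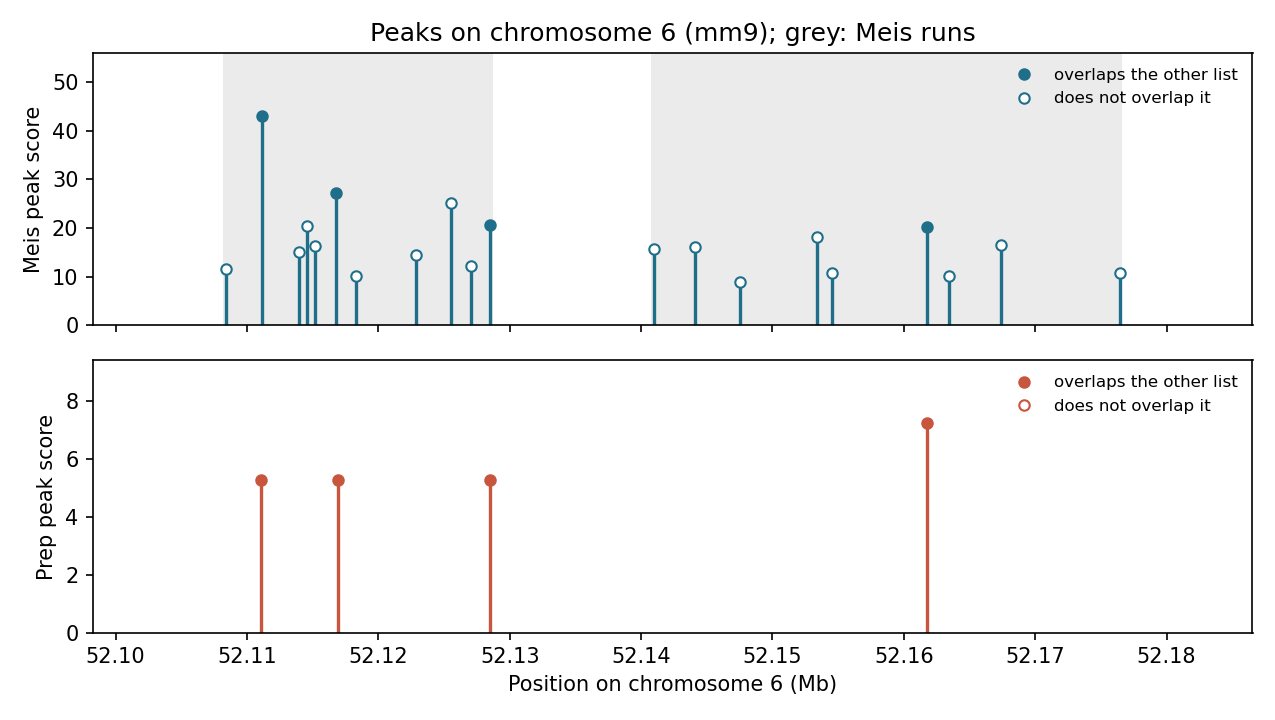
Peaks of the Meis list (upper panel) and the Prep list (lower panel) on chromosome 6 between 52098281 and 52186538 (mm9, x axis in Mb), drawn at their centres with the peak score as height; the scales of the panels differ and are not comparable. Grey bands mark the Meis runs of 11 and 9 peaks. The 4 Prep peaks in the window all lie on Meis peaks, and 16 of the 20 Meis peaks have no Prep partner.

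Peaks in Meis runs were shared more often than the other Meis peaks, though most had no Prep partner. Over the 13 runs 18 of 78 peaks were shared (23.1%, 15.1 to 33.6%), against 389 of 5608 outside them (6.94%; Fisher's exact test, two-sided, adjusted over both lists, p = 1.29e-05). Neighbouring peaks are not independent, so this p may be too small. The comparison was also not matched for score, and 25.8% of the highest-scoring 10% of Meis peaks were shared. It therefore does not separate lying in a run from having a high score. The 5 named runs held 9 shared peaks of 45. On chromosome 6, 3 of 11 and 1 of 9 Meis peaks overlapped a Prep peak, and the 4 Prep partners had scores between 5.25 and 7.22, all below the Prep median of 10.5. The lowest score in the Prep list is 5.03, so weaker Prep signal at the other Meis peaks would not be listed. The chromosome 11 run had 2 of 10 shared, the chromosome 18 run 3 of 9, and the chromosome 2 run 0 of 6, with 0 Prep peaks anywhere in it. The run with the largest shared part was chosen after its values were seen. It lay on chromosome 8 at 28095188 to 28119834, where 4 of 5 Meis peaks were shared.

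The Prep list held 7 runs with 29 peaks, against 0.018 runs expected and 2 at most under random placement (one-sided permutation p = 0.001). The limit of even placement given for the Meis runs holds here too. Of the peaks in Prep runs 3 were shared (10.3%, 3.58 to 26.4%), against 12.3% of the Prep peaks outside runs, a difference that did not pass the test (Fisher's exact p = 1). The largest, on chromosome 5 at 33066553 to 33081852, held 5 peaks, all weak, with scores of 5.25 to 7.88. The next 4 runs held 4 peaks each. On chromosome 7 at 6680236 to 6683352 the top score was 113, and on chromosome 7 at 75273970 to 75275218 it was 102. On chromosome 9 at 21758163 to 21760770 it was 99.8, and on chromosome 5 at 110515304 to 110536828 it was 97.2. The first 3 of these were only 3.12, 1.25 and 2.61 kb long. In the higher-scoring 50% of the Prep list 1 run was left.

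The lists were spread differently over the chromosomes. The chi-square statistic was 191, against a mean of 20 and a highest value of 62.4 with permuted list labels (permutation p = 1e-05, the smallest they can give). Prep had the larger share on 6 of the 21 chromosomes tested and the smaller on 5, at an adjusted Fisher's exact p under the threshold of 0.05. The ratio of shares farthest from 1, among chromosomes with peaks in both lists, was on the X chromosome, with 74 Prep peaks (2.22%, 1.77 to 2.78%) and 40 Meis peaks (0.703%, 0.517 to 0.956%). The Prep share there was 3.16 times the Meis share (Fisher's exact test, adjusted p = 3.5e-08). By the same exact test, Prep shares were also larger on chromosome 17 (5.43 against 3.36%, adjusted p = 2.74e-05), chromosome 11 (8.32 against 5.93%, adjusted p = 7.35e-05), chromosome 7 (8.08 against 5.66%, adjusted p = 5.28e-05) and chromosome 5 (7.93 against 6.28%, adjusted p = 0.00642). By the exact test they were smaller on chromosome 18 (2.40 against 4.24%, adjusted p = 2.74e-05), chromosome 6 (3.90 against 5.86%, adjusted p = 0.000138), chromosome 14 (3.36 against 4.85%, adjusted p = 0.00182), chromosome 1 (5.19 against 7.03%, adjusted p = 0.00145) and chromosome 12 (3.81 against 5.17%, adjusted p = 0.00642). The Y chromosome carried 6 Prep peaks, with a median score of 6.15, and 0 of 5686 Meis peaks, which allows a share of up to 0.0528% by the limit of 3 counts and 0.0675% by the Wilson interval (Fisher's exact test, adjusted p = 0.00591).

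**Figure D3:**
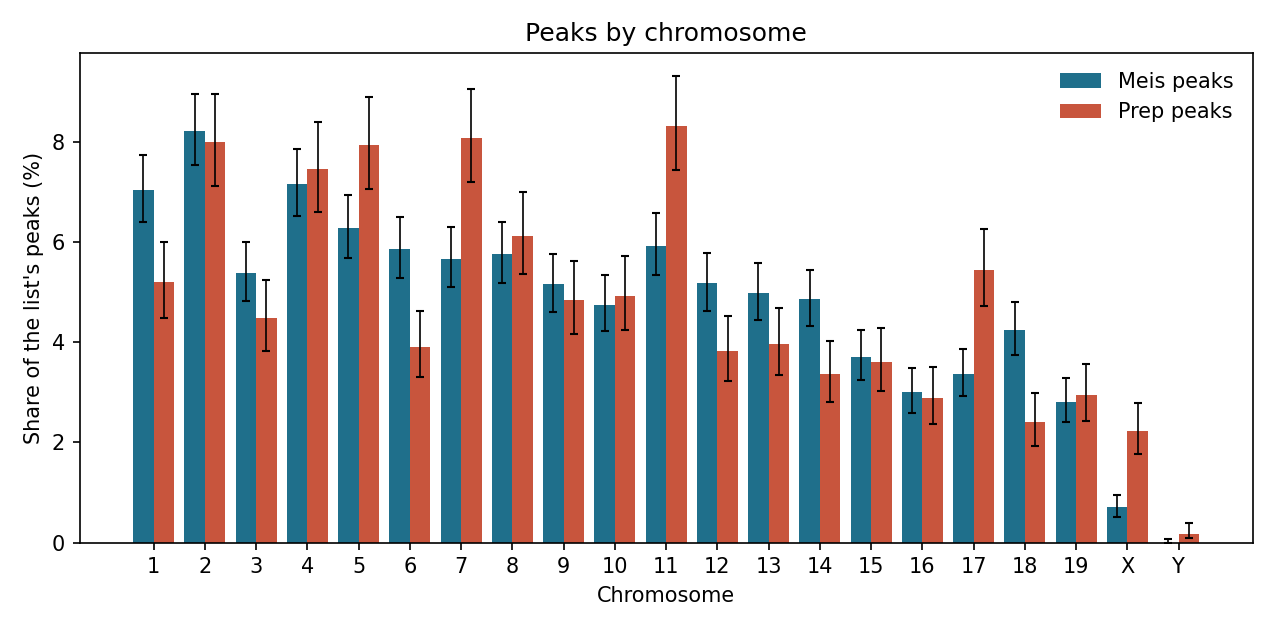
Share of each list's peaks on each chromosome (y axis, percent of 5686 Meis or 3331 Prep peaks); bars are shares and error bars 95% Wilson intervals, which cover the number of peaks only. The Prep bar stands above the Meis bar on chromosomes 5, 7, 11, 17, X and Y and below it on chromosomes 1, 6, 12, 14 and 18, each with an adjusted p under 0.05.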

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

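Of the tests in this part, those of peaks set to 200 bp, of the coefficients of width with score over a common range and of the X chromosome were set before their results were seen, and the others after.

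Over the full lists, shared peaks lay 22.2 percentile points higher in the score order than Meis-only peaks in the Meis list (95% bootstrap interval 19.4 to 24.9) and differed by -11.4 points from Prep-only peaks in the Prep list (-14.0 to -8.80), so that the same contrast goes in opposite directions. The difference between the lists was 33.6 points (29.9 to 37.4). Permutation of the shared label within each list gave p = 0.0001 over 10000 resamples, the smallest they can give. That permutation removes the contrast in both lists, so its p tests for no contrast in either list, not for equal contrasts. The lists were resampled separately, although their shared peaks are paired. Among Prep peaks with at least the 24.7 steps of the lowest Meis peak, the difference of median scores was -10.5 (-23 to 3.94). It did not pass the test (permutation p = 0.185). The lowest Prep peak stood at 7.67 steps. In the highest-scoring 50% of both lists the Prep difference was -23.6 (-31.4 to -15.8, permutation p = 0.00524). Whether the unequal lower limits of the lists shape the Prep contrast was therefore not settled. Low-scoring Prep peaks are wide, but a chance meeting of wide peaks is argued against by random placement: the lower-scoring 50% of the Prep list held 142 more shared peaks than the higher-scoring 50% (275 against 133), where 1000 placements with the same widths gave at most 7 more, while the test with every peak set to 200 bp (difference of medians -3.94, -5.25 to -2.63) decides nothing, since it left 407 of the 408 shared Prep peaks shared. Background regions called in both libraries stay open. The 276 Meis peaks on lower-scoring Prep peaks had a median score 4.23 above Meis-only peaks (3.27 to 5.74), which such regions need not have. Yet in the highest-scoring 10% of the Meis list, whole-step scores, read below as few input reads, were rarer among shared peaks. They were 36.7% of 147 shared and 52.8% of 422 Meis-only peaks (Fisher's exact p = 0.000798). Over the whole Meis list they were 36.9% of shared and 58.3% of Meis-only peaks. Over the whole Prep list they were 97.5% of shared and 93.6% of Prep-only peaks, the other way round. The whole-list shares were not tested, and none of these shares was matched for score. Scores in the highest-scoring 10% of the Meis list ran from 17.9 to 75.1, and 53 of the 100 highest Meis peaks were shared. The test in that slice thus does not separate being shared from having a high score. A Prep antibody that also takes down Meis and true joint binding at lower Prep occupancy cannot be told apart, since both predict more overlap at strong Meis peaks, where it was 25.8% in the highest-scoring 10%; the strong Prep-only peaks need another source in either case.

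Prep peaks of low score were wide, while Meis peaks varied little in width. A candidate explanation is that few reads make the caller's interval wide. Over the range of score steps that both lists cover, the Spearman coefficient of width with score was -0.13 for Meis and -0.71 for Prep, which the explanation was held to forbid; but the quartiles of the Meis peaks there are 27 and 39.5 steps and those of the Prep peaks 41 and 134, so the coefficients are not comparable and that bound was wrong. At equal steps the median widths were close, with 212 bp for Prep and 211 bp for Meis below 50 steps, and the largest difference, above 100 steps, was -15 bp (-26 to -11). The wide Prep peaks, with a median of 277 bp, are the 1996 below the lowest Meis step number, so that the width may follow the step number rather than the protein; steps are read below as a ratio of reads, so the read number itself was not tested.

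The X chromosome took a larger share of Prep than of Meis peaks. The Meis list begins at a higher number of steps, which might remove weak X peaks. Prep peaks with at least as many steps as the lowest Meis peak still had 2.55% on the X chromosome (1.83 to 3.54%, 34 of 1335), against 0.703% for Meis (Fisher's exact p = 1.04e-07), which argues against that as the whole cause. Equal steps of the lists are not known to mean equal strength, so this holds for a limit in steps only. A difference between the proteins, or between the single libraries, stays open and was not tested.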

How the results depend on the processing

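Of 43 alternative values, 31 kept their direction and their side of the threshold or, for counts, stayed within 1.5 times, 11 counts moved by over 1.5 times, 1 difference lost its call and 0 reversed; chosen after seeing the data were the equal score steps, the moved Prep peaks, autosomes outside the peak numbers, the 200 bp width for the score differences, the stricter list for the runs, and all settings of the chromosome comparison. Some of the 31 could hardly change. The Meis list cut at the steps of its own lowest peak holds 5686 peaks by definition. Moving Prep peaks by 10 to 100 kb replaced only the random placements. The observed 407 Meis and 408 Prep peaks of that setting could therefore not change. The 200 bp width left 407 of the 408 shared Prep peaks shared. The highest-scoring 50% left 2843 Meis and 1665 Prep peaks by construction, with 89 shared peaks in each list against 0.796 expected, 7 Meis runs and 1 Prep run. Its score differences were 1.90 for Meis and -23.6 for Prep, against 3.58 and -3.94 in the full lists. Peaks with at least the steps of the lowest Meis peak were 1335 for Prep, and 90 Meis and 92 Prep peaks were then shared against 1.22 expected. The Meis score difference was 1.23 (0.115 to 2.81), and the Prep score difference was -10.5 and no longer passed the test (permutation p = 0.185). The highest-scoring 50% passed with 89 shared peaks (permutation p = 0.00524). The intervals of these Prep differences overlap, at -23 to 3.94 for equal steps and -31.4 to -15.8 for the highest-scoring 50%. The settings also differ in their Meis lists and were not compared, so the reason for the lost call is not known. The range of permutation p over the other Prep alternatives was 0.00012 to 0.00524. Gaps of up to 50 kb gave 107 Meis and 54 Prep runs, against 7.42 and 1.29 expected. Overlap of 50% of each peak, centres within 200 bp and intervals within 1 kb were other overlap rules. These, equal list lengths, peaks of 200 bp and autosomes alone gave 330 to 464 shared Meis and 330 to 472 shared Prep peaks. Each count had a permutation p of 0.001. The moved Prep peaks themselves gave 5.49 shared Prep peaks on average and 17 at most, against the observed 408 (permutation p = 0.001). The chromosome statistic was 142 to 154 under its 3 alternatives. No paired analysis was possible because each group has 1 library. No replicate could be left out for the same reason. The planned placement by distance to genes, the promoter shares, motifs and gene lists, and the alternatives for them, were not run without an mm9 genome. Read depth is unknown, so the precision of a single peak could not be given.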

Other observations

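All tests in this part were chosen after the values they rest on were seen.

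Peak scores fell on a regular ladder. In the Meis list 56.7% of scores were whole multiples of 0.345, and in the Prep list 94.1% were whole multiples of 0.657. A match meant within 0.001 of a step, where evenly spread scores and an independent step would give 0.2%. Each step was taken from the most frequent scores of its own list and adjusted to the highest one. Scores were often tied, with 861 distinct Meis and 478 distinct Prep values, so the whole-step shares are partly fixed in advance. Of the remaining scores of both lists, 63.0% were whole sixths of a step, where evenly spread scores would give 1.0%. This is consistent with a score that is a ChIP read number divided by an input read number, times 1 factor per list, which is a hypothesis about the caller's output. The lowest Meis peak stands at 24.7 steps and the lowest Prep peak at 7.67, and the highest at 218 and 538. On the reading above these are ratios of reads, so they do not give the number of reads behind a peak.

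The 5 Meis runs with most peaks lay on chromosomes 6, 11, 18, 6 and 2. The Hox genes, which set position along the body axis and whose products bind DNA with TALE proteins, lie on chromosomes 2, 6, 11 and 15 in the GRCm38.p6 gene table, where 39 of 39 listed Hox genes were found. With 4 of the 5 runs on these chromosomes, which carry 23.7% of Meis peaks, the one-sided exact binomial p was 0.0128, with the 2 runs on chromosome 6 being neighbours and not independent. The smaller Meis runs were left out of this test. They lay on chromosomes 2, 5, 8, 11, 15 and, more than once, 14. Chromosomes alone do not tell whether the runs lie in Hox clusters. The positions of runs and Hox genes were not compared, since the gene table belongs to another build than the peaks.

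Of the Prep peaks, 3 were wider than 1000 bp. The widest, on the X chromosome at 36308740 to 36314072, was 5333 bp wide with a score of 5.25. The others lay on chromosome 4 at 43070569 to 43072580 (2012 bp) and on chromosome 3 at 51363835 to 51365388 (1554 bp). In the Meis list 0 peaks exceeded 1000 bp, and the widest was 686 bp.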
